A study of Escherichia coli with 2 samples.

How the data were processed

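Binding of SopB, also called ParBF, the centromere-binding protein of the F plasmid partition system, was measured by chromatin immunoprecipitation and sequencing in *Escherichia coli* strain DLT1215 carrying the plasmid pOX38B. Per the labels, cultures in LB medium at 37 °C and an optical density of 0.5 were fixed with 1% formaldehyde, sonicated, and immunoprecipitated with affinity-purified anti-SopB antibody. Libraries were made with 130-bp adapters and sequenced for 50 cycles. The Input library had no antibody. There was 1 Input library and 1 immunoprecipitated (IP) library.

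The deposited values are tag counts per base, given by the authors in 8 files, for the forward and reverse strands of the plasmid and chromosome in each library. Per the submitters' processing notes, the tools were BWA 0.6.2 and SAMtools and the genome build was ASM584v2. Mapping filters and the handling of duplicates are not given in the sources used here. The values were whole numbers that differed in total between libraries, as raw counts do. The last chromosomal tag lay at position 4639171 in the Input and 4639170 in the IP. The last gene of the ASM584v2 gene table ends 2457 bp beyond the last Input tag, and 8 insH copies in that table lie 815 to 2409 bp away from the nearest tag-free stretch of matching length. Positions are therefore given as in the deposited files, and no gene of that table was assigned to a position. Motif sites, gene lists, and the gradient between origin and terminus had been planned with an annotated sequence and were not analysed here. No plasmid annotation was used here.

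Tags of both strands were summed in 100-bp bins on the plasmid and 500-bp bins on the chromosome, and bins with fewer than 20 Input tags were left out. Ratios of IP to Input tags were scaled by the chromosomal tags of each library, which multiplied the raw ratio by 1.11. The enriched domain ran from the summit outwards until more than 1 kb lay below a ratio of 2. Excess ratios were taken over the median of plasmid bins more than 20 kb from the summit along the sequence in the files, called distal bins. Power-law and exponential curves on the log10 excess, and a straight line on the untransformed excess added after seeing the data, were fitted by least squares to bins 500 bp to 10 kb from the summit, on each side. A chromosomal bin was called enriched at a ratio of at least 2, and depleted at 0.5 or less, with the whole interval beyond 1. Intervals are exact 95% intervals, Clopper-Pearson for shares and conditional binomial for ratios.

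With 1 library per group there is no replicate error and no test between conditions, and all intervals cover counting error only. Tags shared positions more often than independent reads would. In the Input 80.3% of chromosomal positions on each strand carried tags, against 98.6% for a Poisson spread, and in the IP 55.3% against 97.8%. The estimated number of tags per molecule was 2.61 in the Input and 4.74 in the IP, on the assumption of even coverage, so that uneven coverage and repeats without tags raise it. Intervals with counts divided by these numbers were also computed for named bins and are wider.

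Regions named in the text followed a rule fixed before the data were examined. On the plasmid the rule took the summit bin, the bins nearest 1, 2, 5, 10 and 20 kb on each side, the ends of the domain, and up to 10 bins under 0.6 of the median of the 20 bins around. On the chromosome it took the 15 highest and 5 lowest bins, with adjacent bins merged. Other positions in the text were chosen after their values were seen. Alternatives covered the strand, duplicates, scaling, bin size, tag shift, thresholds, Input minimum and fitted distances.

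The procedure was tested on simulated data. For chromosomal bins, 9132 bins were drawn with 4 tags per molecule in the IP. Of the 100 bins planted at 3-fold 100% were called, as were 100% of those planted at 2.5-fold, with 0 other bins. Planted bins were well covered in the Input, both folds lay above the threshold of 2, and other bins varied by counting noise and duplicates only. The simulation therefore checks the procedure, not the recovery in bins with few Input tags or the false calls in real libraries. For the domain length, a simulated span of 24953 bp over 606 plasmid bins was recovered as 24600 bp. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.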

Results

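The SopB protein of the F plasmid binds the plasmid centromere, sopC, and the series asks where it lies along DNA in growing cells. Tag counts from 1 anti-SopB IP library were compared with those of 1 Input library from the same strain and plasmid. The Input held 43957716 tags, 90.6% of its 48502096 reads passing filter, and the IP held 45430400, 89.2% of 50921857. There were no replicates, so each interval given is a 95% interval for counting error in these 2 libraries.

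The plasmid took a larger share of the IP than of the Input. Plasmid tags made up 22.1% of mapped tags in the IP (22.10% to 22.12%) and 10.3% in the Input (10.31% to 10.33%), a ratio of shares of 2.14 (2.141 to 2.146). Scaled by chromosomal tags, the plasmid as a whole was 2.47-fold enriched (2.46 to 2.47). The gain was uneven along the plasmid. A domain of 17.5 kb held 61.0% of plasmid tags in the IP and 26.2% in the Input, and its scaled ratio was 5.74, against 1.31 for the rest of the plasmid.

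The highest ratio was at positions 52401 to 52500, beside a stretch of 543 bp without tags in either library, at positions 51943 to 52485. In that bin the IP was 13.6-fold over the Input (12.8 to 14.4, and 12.32 to 15.03 with counts divided by tags per molecule), from 14601 IP and 1198 Input tags. The bin was 10.3 times the median of distal bins. Of its positions, 85 carried no Input tag, so the value rests on the remaining ones at the edge of the stretch. Its ratio was 8.17 on the forward strand and 20.1 on the reverse strand. With forward tags alone the highest bin lay on the other side of the stretch, at positions 51901 to 52000, with a ratio of 16.1. The highest bin in which every position carried Input tags, chosen after seeing the data, was the next one, at positions 52501 to 52600, with a ratio of 10.9 (10.7 to 11.2).

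**Figure D1:**
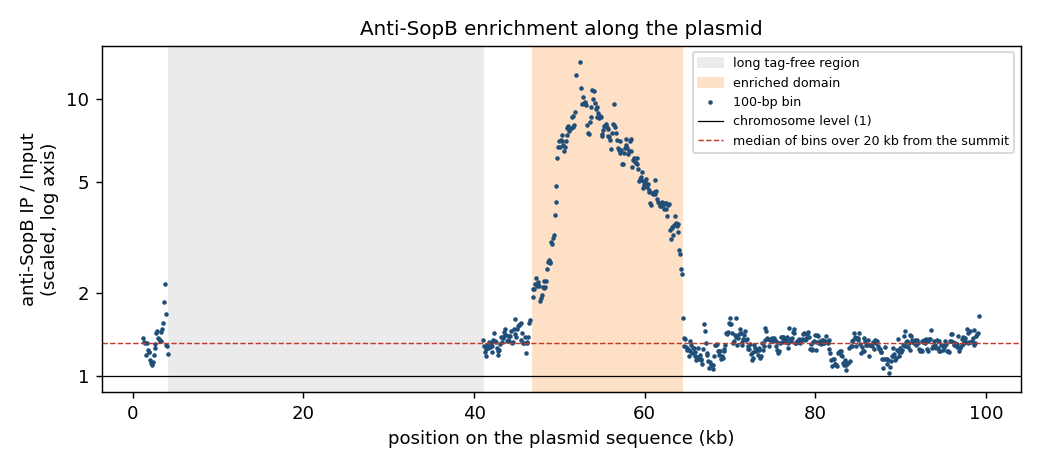
Scaled ratio of anti-SopB IP to Input tags (log axis) in 100-bp bins against position on the plasmid in kb; each point is a bin, with 1 library per group. The ratio peaks at 13.6, and bins over 20 kb from the summit have a median of 1.31, above the chromosomal level of 1.

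SopB enrichment covered a domain from position 46901 to position 64400. Bins at or above 2 made up 16.8 kb of the 17.5 kb. Of the others, 3 bins at positions 47701 to 48000 had ratios of 1.865 to 1.957, and 4 bins inside the 543-bp stretch had no ratio. The domain was asymmetric. It reached 5.55 kb to the left of the summit and 11.9 kb to the right, and 74.1% of the excess IP tags in it lay to the right and 25.9% to the left. Most of the 543-bp stretch lies left of the middle of the summit bin and adds no tags, so the right-hand share may be too high. Outside it, the 297 distal bins had a mean ratio of 1.31 ± 0.11 (SD across bins) and ranged from 1.03 to 2.15. Distances follow the sequence in the files, in which positions 4196 to 41047 held 11 Input and 174 IP tags. The plasmid had 75.8 Input tags per covered base pair, so these counts argue against that sequence being present in these cells. With that sequence absent, the 30 distal bins at positions 1201 to 4200 lie 11.3 to 14.2 kb to the left of the summit. Without them, a choice made after seeing the data, the distal median was 1.31 and the highest distal bin 1.66. That bin, at positions 99101 to 99200, is the last with a ratio and rests on 625 Input tags. Distances were not measured across the ends of the sequence. On a circular plasmid, other distal bins near the right end may therefore also lie closer to the summit. A stretch of 274 bp without tags, at positions 46551 to 46824, lay just outside the left end. No bin of the 171 in the domain fell below 0.6 of its surroundings. The lowest relative value was 0.78, at positions 53401 to 53500, with a ratio of 7.43. The length followed the threshold, from 13400 bp at a ratio of 4 to 19800 bp at 1.5, and was 100 bp with tags capped at 1 per position, where counts on the plasmid are saturated.

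Enrichment extended farther to the right of the summit than to the left. To the left, the ratio was 8.60 (8.41 to 8.80) at 1 kb from the summit, 6.80 (6.63 to 6.97) at 2 kb, 2.20 (2.13 to 2.26) at 5 kb and 1.34 (1.30 to 1.39) at 10 kb. To the right it was 7.43 (7.26 to 7.61) at 1 kb, 8.56 (8.35 to 8.78) at 2 kb, 5.84 (5.70 to 5.98) at 5 kb, 3.99 (3.89 to 4.10) at 10 kb and 1.20 (1.17 to 1.24) at 20 kb. At 1 kb the left bin was higher than the right, and at 2, 5 and 10 kb the right bin was higher. The intervals did not overlap, but they cover counting error in single bins, and neighbouring bins differed by more. The right-hand bin at 1 kb is the lowest of the domain relative to its surroundings. Nearby, the ratio was 9.48 in the bin starting at 53101 and 8.60 at 53601, and on the left 7.67 at 51101. The order at 1 kb therefore depends on the bin. The bin nearest 20 kb on the left lay at positions 41001 to 41100, where coverage began, much closer to the summit than 20 kb. Its ratio was 1.35 (1.13 to 1.61), from 236 Input tags. With counts divided by tags per molecule the interval was 0.955 to 1.89, which includes 1.

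Changes of the ratio over short distances were also read from the profile, at positions chosen after seeing it. Over the 500 bp on each side of position 49601 the ratio went from 3.48 to 6.21, moving to the right. At position 53701, to the right of the summit, the ratio was 7.93 before and 10.04 after, while Input tags changed 0.771-fold and IP tags 0.976-fold. Across position 46601, where the windows include the 274-bp stretch, it went from 1.43 to 2.03. Between 46601 and 49601 it was 2.06 in the bin starting at 47001, 2.25 at 47201, 1.865 at 47701, 2.11 at 48001, 2.44 at 48501, 3.04 at 49001 and 4.23 at 49501. At the right end of the domain it went from 2.64 in the 500 bp before position 64401 to 1.38 in the 500 bp after it. Input tags rose 1.68-fold there and IP tags changed 0.875-fold. The window before includes part of an 87-bp stretch without tags, at positions 63875 to 63961, which lowers both counts in it.

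**Figure D2:**
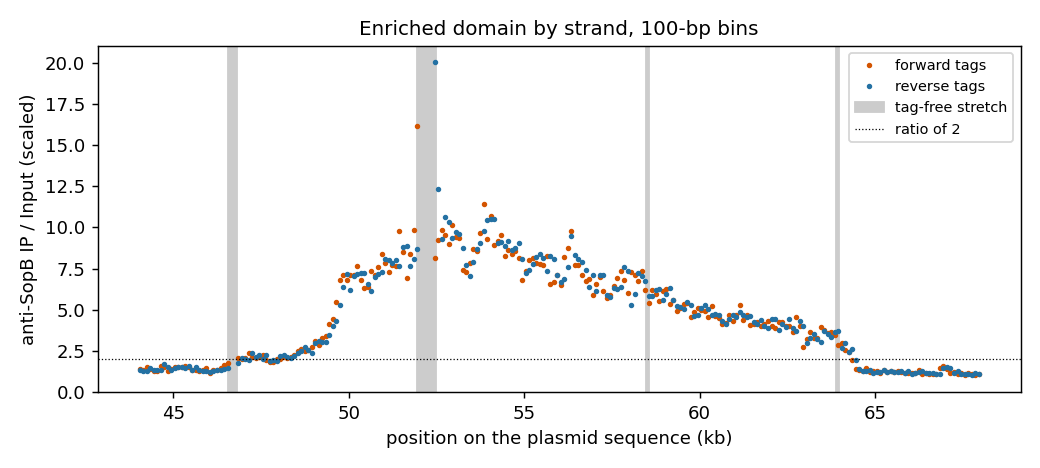
Scaled ratio of anti-SopB IP to Input in 100-bp bins from 44 to 68 kb of the plasmid, for forward and reverse tags. Grey bands are stretches without tags. Strands follow each other over the domain, and separate beside the 543-bp stretch, where the reverse ratio reaches 20.1.

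Over 500 bp to 10 kb, an exponential had a higher R2 than a power law on each side, both fitted to the log10 excess. To the right, R2 was 0.908 for the exponential, with a 1/e length of 8.28 kb, and 0.732 for the power law, with a slope of -0.41 ± 0.026 (SE). To the left, R2 was 0.792 for the exponential, with a 1/e length of 1.43 kb, and 0.705 for the power law, with a slope of -2.43 ± 0.17. On the left 6 bins at or under the distal median were left out, and with nothing subtracted the power law had the higher R2 on that side, the 1/e length was 4.41 kb and the power-law slope -0.90. Over 0.5 to 5 kb the power-law slopes were -1.31 on the left and -0.19 on the right. A straight line fitted to the untransformed excess, added after seeing the data, had an R2 of 0.882 on the right and 0.730 on the left, which cannot be ranked with those of the log10 fits. Bins are not replicates, so R2 and the SEs describe these profiles only. The SEs treat neighbouring bins as independent, so they may be too small, and they are not intervals for counting error.

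**Figure D3:**
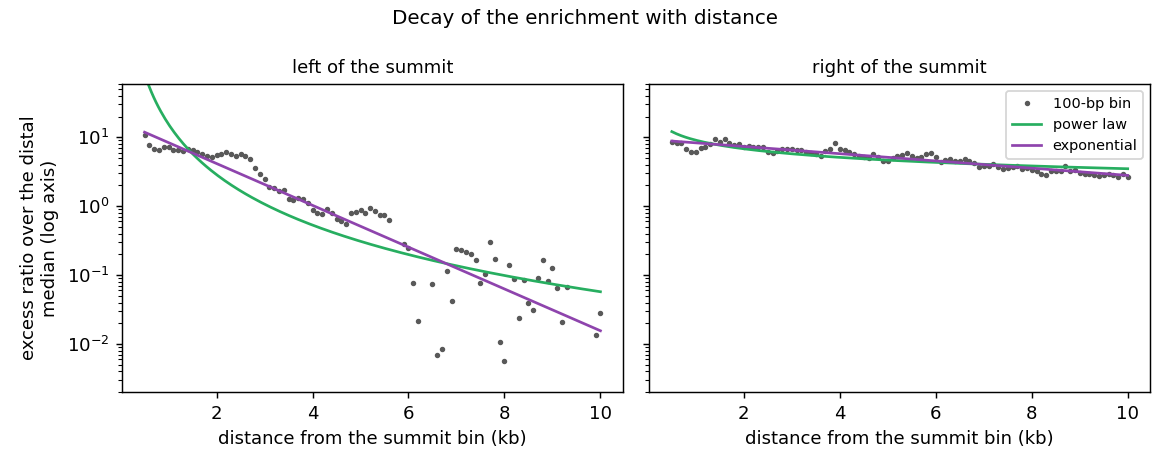
Excess ratio over the distal median (log axis) against distance from the summit bin in kb, to the left and right; points are 100-bp bins and lines the fitted power law and exponential. The right side declines with a 1/e length of 8.28 kb and the left with 1.43 kb.

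The chromosome carried no domain of comparable height. Of 9132 bins, 6 were enriched and 0 depleted. The counts of enriched and depleted bins were 4 and 0 with forward tags alone, 11 and 1 with reverse tags alone and 15 and 2 in 200-bp bins. In 1-kb bins 3 were enriched, and among 500-bp bins with at most 100 tag-free positions, a limit set after seeing the data, 1 was. The mean ratio was 1.01 ± 0.099 (SD across bins), and the highest bin, at positions 3943001 to 3943500 with 427 tag-free positions, reached 2.13, against 13.6 on the plasmid. Of the 6 enriched bins, 4 had more than 200 positions without Input tags. Scaling by reads passing filter multiplied every ratio by 0.855, which put the highest bin at 1.82 and left 0 bins at or above 2.

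The 15 highest bins formed 13 regions, of which 9 had more than 200 tag-free positions per bin. The other 4 were at positions 2816001 to 2816500, with a ratio of 2.08 (2.01 to 2.16), 3980001 to 3980500, with 2.01 (1.95 to 2.07), 2349501 to 2350000, with 1.84 (1.76 to 1.92), and 1607001 to 1607500, with 1.76 (1.68 to 1.85). In these 4 regions the centre of the forward excess lay 101 to 146 bp to the left of that of the reverse excess. Such an offset does not mark SopB binding. Among lags of at least 30 bp, the best on the chromosome was 102 bp in the Input and 100 bp in the IP. The 2 libraries include no control IP, so SopB binding at these positions was not tested. Among the regions with many tag-free positions, 3422001 to 3422500 had a ratio of 2.11 (1.90 to 2.35), and the merged region 3943001 to 3944500, which holds the highest bin, had 1.98 (1.90 to 2.07). The lowest bins formed 4 regions with ratios of 0.67 to 0.71, the lowest at 1295001 to 1295500 and the others at 446501 to 447000, 756501 to 757500 and 758001 to 758500. Ratios varied with Input tags across chromosomal bins. Among 9083 bins with at least 1000 Input tags, the median log2 ratio was 0.070 in the lowest 10% by Input tags and -0.090 in the highest 10%. Bins with fewer tags, such as 3422001 to 3422500 with 536, were outside that set. Neither the highest nor the lowest bins were adjusted for this trend. No gene is assigned to these positions, because the gene table used another sequence version.

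**Figure D4:**
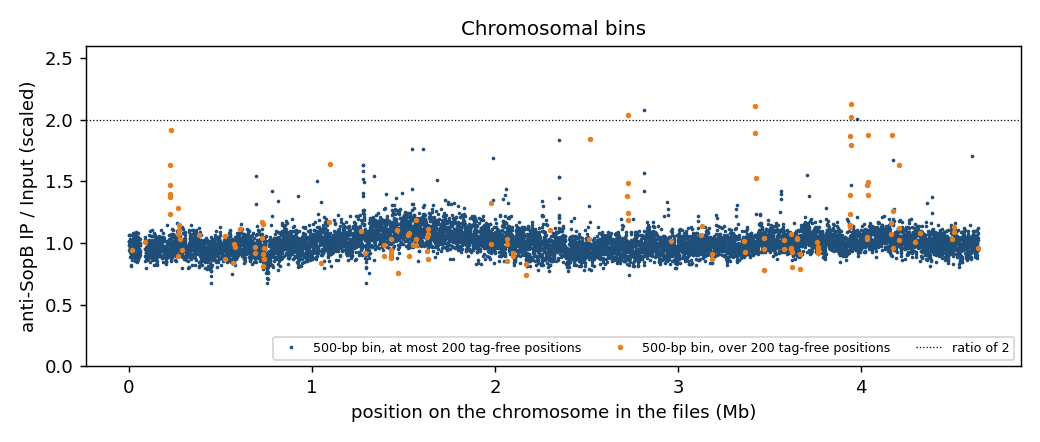
Scaled ratio of anti-SopB IP to Input in 500-bp bins against position on the chromosome in Mb; orange points are bins with more than 200 positions without Input tags. Of 9132 bins, 6 lie at or above 2, and 4 of these are orange.

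Forward and reverse tag profiles correlated best at a lag of -52 bp in the Input, on the plasmid domain and the chromosome. In the IP the lag was -49 bp on the domain and -52 bp on the chromosome. Among lags of at least 30 bp, the best were 112 bp on the domain and 102 bp on the chromosome in the Input, and 99 bp and 100 bp in the IP. Correlations were low on the chromosome, 0.14 in the Input and 0.064 in the IP at the best lag.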

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

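Both counts here, and the window of the cluster, were chosen after the data were seen. With 1 library per group, no library could be compared with others of its group. A long region of the plasmid sequence, positions 4196 to 41047, held almost no tags and entered no ratio, yet the IP had 174 tags there, on 41 positions, against 11 tags on 6 positions in the Input. The scaled ratio was 17.6 (9.61 to 36.0). A chromosomal region without coverage, positions 62386 to 88219, held 175 IP tags on 43 positions and 3 Input tags, a ratio of 65.0 (21.9 to 318). Of these, 131 IP tags on 31 positions fell within positions 70070 to 71464, as did all 3 Input tags. Where the tags of either region came from was not tested, DNA of another library or a vector was not excluded, and the ratios are not read as measures of SopB binding.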

How the results depend on the processing

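Limits on tag-free positions, distal bins on only 1 side of the long tag-free region and distances from the middle of the tag-free stretch were chosen after seeing the data, and all other alternatives before the data were examined. With forward tags alone the ratio of shares was 2.14, the summit 16.1 and the right-hand share of excess tags 73.6%, and 4 chromosomal bins were enriched. With reverse tags alone the ratio of shares was 2.15, the summit 20.1 and the right-hand share 75.1%, and 11 chromosomal bins were enriched. With tags capped at 1 per position the ratio of shares was 1.44, the summit 1.64, the domain 100 bp, the chromosomal bins 0, the lag 0 bp and, on the left, R2 of the exponential minus that of the power law -0.015, the 1/e length -21.2 kb and the power-law slope 0.37. These capped values say nothing about stability, since 99.8% of covered plasmid positions carried tags in each library and 0 of the 6 enriched chromosomal bins could have reached 2. Capping gave no value for the asymmetry or the right-hand 1/e length. Scaling by reads passing filter gave a summit of 11.6, a domain of 15900 bp, a distal median of 1.12 and 0 chromosomal bins, as it multiplies every ratio by 0.855. Shifting tags by 75 bp gave a summit of 17.7 and a right-hand share of 74.3%, and 500-bp bins gave 74.2%. Distances from the middle of the tag-free stretch gave 74.1%. The highest bin without a tag-free position was 10.9. The domain was 19800 bp at a ratio of 1.5, 13400 bp at 4 and 15200 bp at 2 times the distal median, as a threshold sets it. The 1/e length on the right was 10.2 kb over 0.5 to 5 kb and 10.6 kb with nothing subtracted, where the left difference in R2 was -0.069. Chromosomal bins numbered 15 in 200-bp bins, 3 in 1-kb bins, 35 at a ratio of 1.5, 0 at 3, and 1 among bins with at most 100 tag-free positions. Where no reason is given, the cause was not tested. The right-hand share stayed above 50% in each alternative that gave one. Of the alternative values, 70 stayed within their interval or tolerance, 47 moved and 4 reversed. The 70 include settings with almost no effect, so the tally does not measure stability. Input minima of 5 and 50 gave the same summit and domain length, and distal bins on only 1 side left the distal median at 1.31. Tolerances, set after the data were seen except the last for counts, were 1 bin at each domain end, 5 bp for lags, 1 SD for the distal median, and 1.5 times for counts and differences in R2. Motif sites, gene lists and the origin to terminus gradient were not run, for want of a matching sequence. No paired analysis was possible because each group has 1 library.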

Other observations

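All tests in this part were chosen after the results were seen. In the Input, the plasmid had 75.8 tags per covered base pair and the chromosome 9.06, a ratio of 8.37. In 100-kb windows along the chromosome, the highest median density was at 3.9 to 4.0 Mb and the lowest at 1.6 to 1.7 Mb in both libraries. The highest window was 2.26 times the lowest in the Input and 2.03 times in the IP.

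Another peak stood outside the domain, at positions 3501 to 3900 of the plasmid, next to the long tag-free region, across which its distance from the summit is uncertain. Its ratio was 1.82 (1.80 to 1.84). Its highest bin, 3701 to 3800, had a ratio of 2.15 (2.11 to 2.20). That is 7.47 SD above the mean of distal bins, a set that includes the peak itself. The forward summit lay at 3691 and the reverse summit at 3791, 100 bp apart. The Input also had a best lag of 112 bp on the plasmid domain among lags of at least 30 bp, so this offset does not mark SopB binding.

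Within 50 bp of the tag-free stretch at positions 51943 to 52485, forward tags were more enriched than reverse tags on the left (15.5 against 8.65) and reverse more than forward on the right (16.6 against 8.84). The highest mean inward asymmetry at the other 3 tag-free stretches was 0.052 on the log2 scale, against 0.88 here. These values come from ratios of IP to Input, in which an alignment edge effect common to both libraries would cancel. The low values at the other stretches therefore cannot test such an effect. Protein bound inside the stretch stays open as a hypothesis: the lower inward asymmetry of the flanks was 0.84, but these flank values are the pattern itself and cannot test it. Whether the stretch holds the repeats of sopC is also open, since no plasmid annotation was used here.

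The ratio fell by 0.94 on the log2 scale at position 64401, while Input tags rose 1.68-fold and IP tags changed 0.875-fold. The window before the fall includes part of the 87-bp tag-free stretch at positions 63875 to 63961, so both of these fold changes are affected. A rearrangement junction at the fall would leave a gap in coverage, but 0 Input positions were without tags from 64201 to 64700. That window leaves out the 87-bp stretch. Around it the ratio was already falling, from 3.55 in the bin starting at 63801 to 2.84 at 64001. A junction at the 87-bp stretch was therefore not tested. Higher Input density after the fall could lower the ratio, but distal bins matched on Input density differed by -0.26 on the log2 scale. The density before the fall was lowered by that stretch, so the matching is approximate. Input density may account for part of the fall and not for all of it. No biological explanation was tested, and a barrier to spreading remains a hypothesis without a test here.

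A tag-free stretch of 274 bp at positions 46551 to 46824, just left of the domain, could be an exact repeat or a sequence these plasmids lack. Forward and reverse edges differed in 4 of 4 comparisons of edges and libraries, by 6 bp in total, which an exact repeat whose reads were not placed does not predict. The differences were 1 and 2 bp in each library, so the comparisons are the same 2 edges seen in 2 libraries and are not independent. Edges also differed in 4 of 4 at the long tag-free region of the plasmid, and in 0 of 4 at each of the other 3 short stretches. On the chromosome 83.3% of 132 edges of tag-free stretches were equal between strands, and both edges differed in 2 of 66 stretches. The hypothesis that this sequence is absent from the plasmid in these cells predicts such edges, and an imperfect repeat stays open.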
